A study of Mus musculus with 72 samples.

How the data were processed

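Total RNA from the livers of male and female C57BL/6J mice was labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols. Groups were taken from the sample titles: sex and 1 of 6 diets, 12 groups of 6 arrays, 72 in all. The labels also give each array's wash bath, with 3 baths that each hold 1 to 3 arrays of every group, and wash bath was treated as a technical batch.

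The deposited values are log2 intensities, 33847 probes by 72 arrays. The submitters' processing notes name Agilent Feature Extraction 10.10.1.1 and limma, without their order or role. The filter that led to 33847 probes is not given in the sources used here. The values themselves show more. After sorting, every column of the deposited log2 table holds the same numbers (largest difference 0), as quantile normalization leaves them, so any change in the total amount of RNA or in the overall brightness of an array cannot be seen. All 72 columns have a median of 7.9, with quartiles of 6.26 and 10.34. The wash bath means of each probe are also nearly equal: the median F of wash bath given group was 0.0933, where 20 shuffles of the bath labels gave 0.551 to 1.1, and the median over probes of the largest difference between bath means was 0.00341 log2 units. A bath adjustment before deposit leaves such values, although none is stated in the sources used here. The standard errors below do not account for it beyond the bath term of the model. The table used here holds no detection calls, so fold changes against a dim level near 5 depend on the background and were not turned into bounds.

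The comparisons, tests and rules were written before the data were examined. They assumed a gene name for each probe. The table pairs 0 probes with gene symbols, and no table of probes and genes was used here, so each probe was tested as its own row, the gene lists and the cell type markers chosen in advance were not tested, and the sex-linked genes chosen as a label check were not looked up. The rule for named genes, the 6 highest and 6 lowest changes past the threshold in each comparison, was limited to at most 2 probes that rose and 2 that fell per comparison, since probe names carry no biology.

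Each comparison was made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, two-sided) on the deposited log2 values of all 72 arrays, with the 12 groups and wash bath in the model and 58 residual degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, and calls changed by at least 2-fold were counted too. The labels name 2 control diets without assigning them to test diets, so the reference was the mean of both. The 21 comparisons were each test diet against the controls in each sex, Control2 against Control1, CDHFD against HFD, WDGF against WD and WD against HFD in each sex, the sexes on the control diets, and the sex difference in the response to each test diet. Median standard errors were 0.085 log2 units for a diet against the controls, 0.098 to 0.099 for pairs of diets, 0.069 between the sexes and 0.12 to 0.121 for the interactions. The number of arrays limits this precision.

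The model was tested on simulated data with 200 of the 33847 probes changed. For WD against the control diets in males it recovered 79% of changes of 0.5 log2 units and 98.5% of changes of 1. For CDHFD against HFD in females it recovered 73.5% and 98%, and for the sex difference in the response to WD 49.5% and 92.5%. Between 3 and 12 unchanged probes were called in each run. These rates belong to the simulated data and may not carry over to the real arrays. Among other splits of the real arrays, described below, the highest counts for these comparisons were 988, 36 and 69, with a median of 0.

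Within wash baths, probes called from 2 baths were checked for the same direction in the remaining bath wherever at least 20 were called. A mean over the baths is given where this held for each of the 3, and otherwise the single value. The 2 arrays that oppose their sex label, both in wash bath 2, were kept in these checks. Positions between the sexes were computed from the 200 probes that best separate the labelled sexes. The diet scores and the sets of sex-biased probes, together with their two-sided exact permutation tests and bootstrap intervals (10000 resamples, 95%), were added after the data were seen, in place of the gene lists. They form families of 48 and 16 tests. Figures were drawn with matplotlib 3.10.9.

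The alternatives tried were no wash bath term, the replicate number as a block, repeated quantile normalization, centring on the 75th percentile, leaving out the dimmest 25% of probes, eBayes with trend and robust settings, only the arrays of the groups compared, and either control diet alone as reference. Counts without the 2 arrays that oppose their sex label, and with each array of the groups compared left out in turn, were added after the data were seen, as were the scores of male CDHFD without its replicate 5. Sets were also taken from fits on the defining arrays alone, an alternative added at the same stage. The 2 arrays that oppose their sex label were not relabelled. The alternatives set in advance were not repeated without them.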

Results

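Liver RNA of C57BL/6J mice, an inbred laboratory strain, was hybridised to 72 single-colour Agilent expression arrays after 15 weeks on 1 of 6 diets. The arrays fell into 12 groups of 6, males and females on each diet. The diets were Control1, Control2, a high fat diet (HFD), a choline-deficient high fat diet (CDHFD), a Western diet (WD) and a Western diet with glucose and fructose (WDGF). Mice of both sexes were 11 weeks old at purchase, were allocated to the diets at random after 2 weeks of acclimatization, and were killed at ZT16, in the dark phase of the light cycle. The labels do not number the animals, and the p-values measure the spread between these samples. Each array gave 33847 probe values on a log2 scale from 4.39 to 18.84, with a median of 7.9. Arrays of 1 group correlated with a median Pearson r of 0.9941 across probes. The number of arrays limits the precision: the median standard error of a diet against the control diets was 0.085 log2 units. The file used here names probes and not genes, so probes stand in place of genes throughout.

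Sex was the main axis of the data. The first principal component held 34% of the variance and placed males above 0 and females below 0, apart from 2 arrays. Male Control1 replicate 4 lay at -0.135 and female Control2 replicate 4 at 0.114. The second component held 16.9% and set Control1 apart from WDGF. On the second component, males averaged -0.177 ± 0.078 on Control1 and 0.201 ± 0.023 on WDGF, and females averaged -0.089 ± 0.038 on Control1 and 0.094 ± 0.047 on WDGF (SD, n = 6). Control2 and CDHFD overlapped on it. Males averaged -0.082 ± 0.045 and -0.067 ± 0.112, and females -0.045 ± 0.08 and -0.052 ± 0.067, in that order. On a line through the 200 probes that best separated the labelled sexes, with females at 0 and males at 1, 70 arrays lay on the side of their label, with an SD of 0.067 around their sex. The array labelled male Control1 replicate 4 lay at -0.106 and the array labelled female Control2 replicate 4 lay at 1.053. Both oppose their sex label, and the means of their groups on the second component include them. Labels were kept as deposited, so every comparison with the control diets below includes one or both of these arrays, and its count without the 2 arrays is given beside it.

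**Figure D1:**
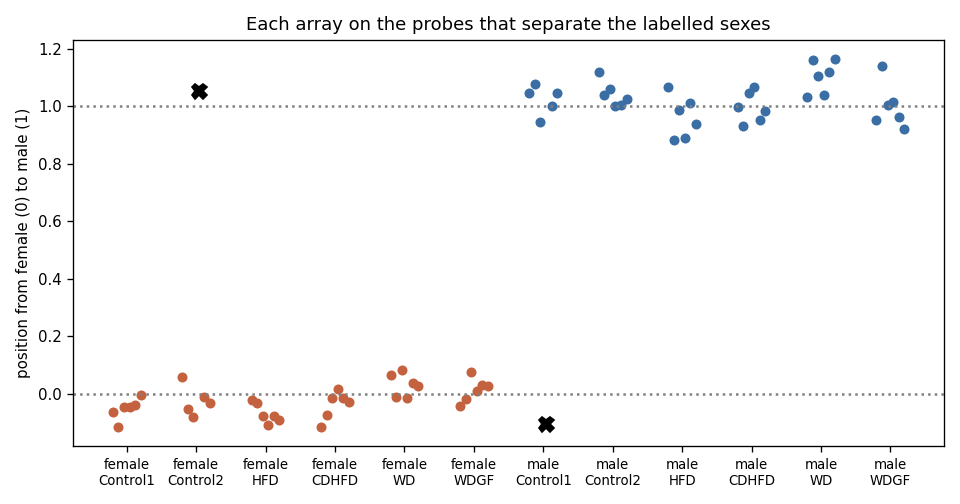
Position of each of the 72 arrays (points, grouped by sex and diet on the horizontal axis) on the line from the female mean (0) to the male mean (1), in units of the distance between the sexes. The crosses mark the array labelled female Control2 replicate 4 at 1.053 and the array labelled male Control1 replicate 4 at -0.106.

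The high fat diet was compared with the mean of both control diets in each sex, since the labels do not say which control belongs to which diet. In males, 6486 probes differed, 3052 higher and 3434 lower on HFD, and 360 of them by at least 2-fold. The 2 largest rises were in probes that are bright in females. Probe A_51_P467076 rose by 6.94 ± 1 log2 units (SE), a 123-fold change, from 7.11 ± 4.38 on Control1 and 7.6 ± 1.73 on Control2 to 14.3 ± 0.97 on HFD (SD, n = 6), while female group means lay between 14.04 and 16.23 (limma, adjusted p = 2.6e-07). Probe A_55_P2044653 rose by 5.97 ± 0.9, and both probes rose by more without the 2 arrays, by 7.83 ± 0.54 and 6.78 ± 0.44. A_55_P2122841 changed by -4.12 ± 0.38, from 13.22 ± 0.98 and 15.47 ± 0.36 on the control diets to 10.23 ± 0.58. In females, 1821 probes differed, 744 higher and 1077 lower, and 76 by at least 2-fold. A_55_P1994112 was 2.97-fold higher in females on HFD, and A_55_P2805919 changed by -3.3 ± 0.57 log2 units (limma, adjusted p = 1e-04). Without the 2 arrays, 7382 probes differed in males and 2123 in females, of which 6209 and 1690 were among those called with all arrays. Of the probes called from 2 wash baths, the 3 batches in which the arrays were washed, a mean of 93.7% in males (range 88.3 to 96.5) and 89.7% in females (79.1 to 96.3) changed the same way in the remaining bath. Among females the count was 613 when only the arrays compared entered the fit, which keeps an array opposing its label. It was 1146 against Control1 alone and 1157 without female HFD replicate 5.

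The choline-deficient high fat diet gave fewer calls. In males, 2615 probes differed from the control diets, 1273 higher and 1342 lower, and 154 by at least 2-fold. The 2 probes that rose most were those of the high fat diet: A_51_P467076 rose by 5.5 ± 1 log2 units and A_55_P2044653 by 4.47 ± 0.9, or by 6.38 ± 0.54 and 5.28 ± 0.44 without the 2 arrays, while A_55_P2122841 changed by -3.85 ± 0.38 (limma, adjusted p = 1.3e-10). In females, 13 probes differed, 4 higher and 9 lower. A_55_P2008437 was 2.47-fold higher, at 7.79 ± 0.95 against 6.59 ± 0.36 on Control1 and 6.39 ± 0.34 on Control2. A_55_P2488169 changed by -1.26 ± 0.2 log2 units, with 6.78 ± 0.3 on CDHFD, 7.6 ± 0.39 on Control1 and 8.51 ± 0.53 on Control2. In females 2761 probes had an unadjusted p under 0.05, where about 1692 of 33847 probes would with no change. The counts were 2848 in males and 36 in females without the 2 arrays. The female count depended on the reference, with 0 probes against Control1 alone and 186 against Control2 alone, and with single arrays, from 4 without female CDHFD replicate 1 to 19 without female Control1 replicate 5. Female Control2 holds 1 of the arrays opposing their label, and the count against Control2 alone was not repeated without it. With only the arrays compared, which keeps an array opposing its label in each sex, the counts were 1338 in males and 1 in females. Without male CDHFD replicate 2 the male count was 1712. The direction of male calls from 2 baths held in the remaining one for 93.5% (86.9 to 97.5). In females 1 bath could be checked on at least 20 calls: of 43 probes called without wash bath 2, 55.8% had the same direction in it. Wash bath 2 has 2 female Control2 arrays, and 1 of them is replicate 4, which opposes its sex label. The check was not repeated without that array, so the low share may depend on it.

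The Western diet gave larger counts than HFD and CDHFD in both sexes with all arrays, but in females its lead over HFD did not hold under every setting. In males, 9586 probes differed, 4467 higher and 5119 lower, and of the 490 with at least a 2-fold change 367 were higher. A_51_P199168 rose by 7.28 ± 0.44 log2 units, a 156-fold change (limma, adjusted p = 3.6e-20). Its male group means were 5.92 ± 0.49 on Control1, 10.94 ± 1.79 on Control2, 11.93 ± 1.43 on HFD, 11.02 ± 1.23 on CDHFD, 15.68 ± 0.41 on WD and 15.09 ± 0.97 on WDGF, and its female means lay between 5.1 and 5.95. Levels near 5 are at the dim end of the scale, where the size of a fold depends on the background. A_51_P156955 rose in both sexes, by 6.98 ± 0.65 in males and by 3.09 ± 0.65 in females. In females, 2329 probes differed, 1298 higher and 1031 lower, and 96 by at least 2-fold. A_52_P205255 was 5.62-fold higher, at 11.18 ± 0.58 on WD against 8.45 ± 0.41 on Control1 and 8.99 ± 0.67 on Control2. A_52_P669922 changed by -6.23 ± 1.01, with a spread of 3.91 within the WD group around its mean of 9.09. With the 2 arrays left out, 10694 probes differed in males and 2229 in females. Calls from 2 baths kept their direction in the remaining bath for 93.9% in males (88.3 to 98.1) and 91.7% in females (88.9 to 94.8). Against Control2 alone the counts were 5519 in males and 731 in females, and HFD then gave 2623 in females. Female Control2 holds 1 of the arrays opposing their label, and these counts were not repeated without it. The female count was 933 when only the arrays compared were fitted, which keeps an array opposing its label. It was 924 without female WD replicate 6 and 1311 without female WD replicate 4.

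The Western diet with glucose and fructose gave the highest counts of the 4 test diets in both sexes against the mean of both controls, though in females not against Control2 alone. In males, 13779 probes differed, 6044 higher and 7735 lower, and 1039 by at least 2-fold, 748 of them higher. In females, 4187 probes differed, 2118 higher and 2069 lower, and 239 at 2-fold or more. A_51_P199168 rose 103-fold in males, and A_51_P156955 rose by 6.05 ± 0.65 log2 units in males and by 3.98 ± 0.65 in females. A_55_P2111980 changed by -4.35 ± 0.83 in males, and A_55_P2153517 by -2.95 ± 0.36 in females, to 9.51 ± 0.61 from 13.39 ± 0.55 on Control1 and 11.31 ± 1.12 on Control2 (limma, adjusted p = 3.2e-08). The 2 arrays left out, 14732 probes differed in males and 4152 in females. Calls from 2 baths kept their direction in the remaining bath for 96.1% in males (95 to 98.1) and 92.5% in females (85 to 97.2). Against Control2 alone the female count was 2139, below the 2623 of HFD. That reference holds the array labelled female Control2 replicate 4, which opposes its sex label. The counts against Control2 alone were not repeated without it, so this order may depend on that array.

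**Figure D2:**
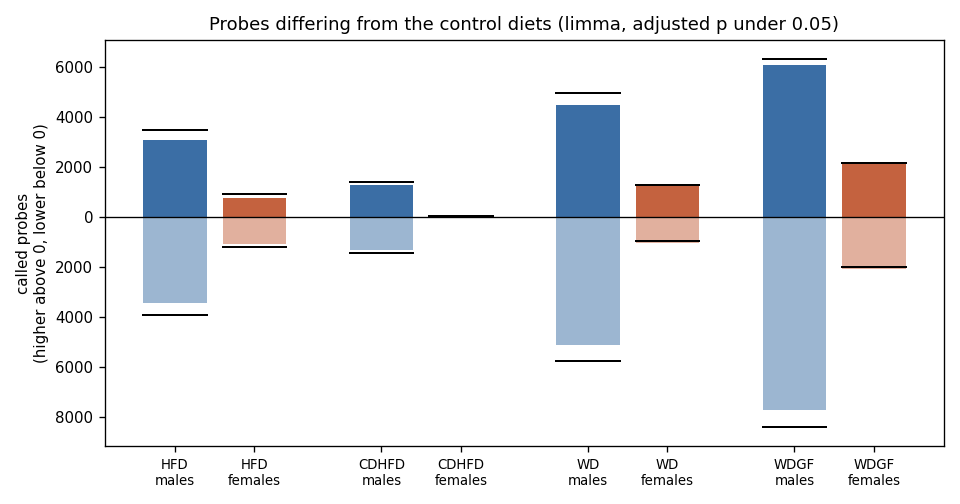
Number of probes that differed from the mean of both control diets (vertical axis, higher above 0 and lower below 0) for each test diet in males (blue) and females (orange), limma at an adjusted p under 0.05, with black lines for the counts without the 2 arrays that oppose their sex label. Counts with all arrays run from 13 in females on CDHFD to 13779 in males on WDGF.

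The 2 control diets also differed from each other. In males, 2100 probes differed, 1260 higher and 840 lower on Control2, and in females 1542 differed, 825 higher and 717 lower. The male probe that rose most was again A_51_P199168, by 5.02 ± 0.5 log2 units or 32.4-fold, followed by A_51_P156955 at 3.17 ± 0.75. A_55_P2153517 changed by -2.94 ± 0.42 in males and by -2.15 ± 0.42 in females (limma, adjusted p = 2.6e-06 and 0.0016). In males the Control1 group and in females the Control2 group held 1 array opposing its label, and without the 2 arrays the counts were 3006 in males and 2704 in females. With only the arrays compared in the fit and these arrays kept, the counts were 410 in males and 58 in females. That fit was not repeated without them. Single arrays moved the female count to 603 without Control1 replicate 3, 752 without Control1 replicate 6 and 883 without Control2 replicate 6, and the male count to 1367 without Control2 replicate 5 and 1397 without Control2 replicate 2. Calls from 2 baths kept their direction in the remaining bath for 87.2% in males (80.2 to 94.8) and 88.8% in females (86.4 to 91.4).

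CDHFD was compared with HFD to address the removal of choline. The labels give only the names of the diets, so other differences between them stay open. In males, 48 probes differed, 8 higher and 40 lower on CDHFD, a count that depends on single arrays. Without male CDHFD replicate 5, 946 probes differed, 253 higher and 693 lower, and the 48 were among them. A_51_P490456 was at 11.79 ± 1.24 on CDHFD and 13.93 ± 0.45 on HFD, a change of -2.22 ± 0.49, with 8.72 ± 0.35 on Control1 and 11.5 ± 1.25 on Control2 (limma, adjusted p = 0.027). A_51_P287198 changed by -1.82 ± 0.36, and A_55_P2114110 rose by 1.23 ± 0.27. In females, 0 probes differed in limma, with 2874 at an unadjusted p under 0.05 (about 1692 by chance). Without the 2 arrays, which are in neither group but enter the shared estimate of the spread, the counts were 117 in males and 1 in females. The male count was 1 when only the arrays compared were fitted, 30 with the replicate number as a block, 28 without the dimmest 25% of probes, and 3 at the lowest with another single array left out, male CDHFD replicate 1 or 6. Of 92 probes called without wash bath 3, 71.7% had the same direction in it.

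Few single probes passed the threshold between the Western diets with and without glucose and fructose, which does not show that few changed. In males, 0 probes differed between WDGF and WD in limma, with 2715 at an unadjusted p under 0.05 (about 1692 by chance), and 0 without the 2 arrays. Without male WD replicate 1, 17 probes differed. In females, A_52_P585907 differed, by 1.18 ± 0.19 log2 units (limma, adjusted p = 0.003), from 5.21 ± 0.45 on WD to 6.36 ± 0.77 on WDGF, both near the dim end of the scale. In females 1641 probes had an unadjusted p under 0.05, fewer than the 1692 of chance. This 1 call was lost with the replicate number as a block, without the dimmest 25% of probes, with only the arrays compared in the fit, and without female WDGF replicate 5 or 6.

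WD and HFD differed in both sexes. In males, 848 probes differed, 442 higher and 406 lower on WD, and in females 1659 differed, 915 higher and 744 lower. A_52_P205255 was 15-fold higher on WD in females, at 11.18 ± 0.58 against 7.28 ± 0.56 on HFD (limma, adjusted p = 3e-16). A_51_P199168 rose by 3.78 ± 0.51 log2 units in males. A_55_P2153517 was lower on WD in both sexes, with changes of -2.81 ± 0.42 in males and -3.31 ± 0.42 in females. The counts were 1123 and 2068 without the 2 arrays, and the male count was 499 without male WD replicate 1 and 503 without male WD replicate 6. Calls from 2 baths kept their direction in the remaining bath for 92.6% in males (86.6 to 100) and 93.4% in females (88.7 to 96.9).

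Males and females on the control diets differed in 9788 probes, 5437 higher and 4351 lower in males, and in 406 by at least 2-fold. A_55_P1952517 was at 14.56 ± 1.46 in females and 6.71 ± 4.72 in males on Control1, and over both control diets it was 342-fold lower in males (limma, adjusted p = 1.5e-12). A_55_P2152607 was 154-fold higher in males, at 14.55 ± 0.13 in males and 7.5 ± 3.4 in females on Control2. The wide spreads belong to the groups that hold the 2 arrays opposing their label. Without these arrays 12622 probes differed, and the changes were -10.29 ± 0.29 log2 units for A_55_P1952517 and 8.63 ± 0.22 for A_55_P2152607. On Control1 alone 5196 probes differed and on Control2 alone 6414. Calls from 2 baths kept their direction in the remaining bath for 89.9% (73.8 to 98.8), lowest for wash bath 2, which holds both arrays.

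The difference between the sexes in the response to each diet was tested as an interaction. It passed the threshold for 387 probes on HFD, 71 on CDHFD, 517 on WD and 2354 on WDGF. A_51_P199168 changed by 7.31 ± 0.63 log2 units more in males than in females on WD and by 6.58 ± 0.62 more on WDGF (limma, adjusted p = 4.8e-13 and 1.6e-11). A_51_P234253 changed by 3.62 ± 0.28 more in males on WDGF: it was at 5.23 ± 0.08 on Control1, 5.35 ± 0.13 on Control2 and 8.93 ± 0.88 on WDGF in males, while female means lay between 5.21 and 5.43. A_55_P2744246 led the list for HFD, at 6.01 ± 0.86, and for CDHFD, at 4.13 ± 0.86. In the other direction, A_55_P1975185 changed by -2.69 ± 0.54 on WD, with male means of 9.05 ± 0.51 on WD and 12.09 ± 1.02 and 12.96 ± 0.72 on the control diets. Leaving out the 2 arrays gave 843 on HFD, 142 on CDHFD, 847 on WD and 3827 on WDGF. Calls from 2 baths kept their direction in the remaining bath for 89.6% on HFD (77 to 100), 88.3% on WD (71 to 97.2) and 92.5% on WDGF (89.3 to 94.2). On CDHFD 1 bath could be checked on at least 20 calls, with the same direction for 72.6% of 84 probes in wash bath 2. The lowest shares on HFD, WD and WDGF were also in wash bath 2, which holds both arrays opposing their label. These checks were not repeated without those arrays. The counts moved further with the reference and the arrays fitted: 257 on HFD, 216 on CDHFD, 322 on WD and 1349 on WDGF against Control2 alone, 36 on CDHFD against Control1 alone, 233, 25 and 344 on HFD, CDHFD and WD with only the arrays compared, and 192 on WD with the replicate number as a block. Each control diet holds 1 of the 2 arrays opposing their label. The counts against a single control diet and those with only the arrays compared were not repeated without them. The lowest counts with a single array left out were 229 on HFD, without female HFD replicate 5, 43 on CDHFD, without male CDHFD replicate 2, and 273 on WD, without male WD replicate 1.

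Of the probes called in females, 93% on HFD, 92.3% on CDHFD, 94.6% on WD and 92.8% on WDGF had a change of the same sign in males, the CDHFD value over 13 probes. Of those called in males, 84.9%, 80.2%, 89.1% and 84.7% had the same sign in females. Across all probes, which are not independent replicates, the male and female changes correlated with a Pearson r of 0.51 for HFD, 0.3 for CDHFD, 0.63 for WD and 0.63 for WDGF, and with a Spearman rho of 0.44, 0.19, 0.59 and 0.58. Without the 2 arrays opposing their label, Pearson r was 0.45, 0.3, 0.62 and 0.6 in the same order. The shares with the same sign and the overlaps below were counted with all arrays. The male and female group means share no arrays, while the bath term and the spread estimated for each probe are common to both. The numbers given below for independent lists do not allow for that common spread. Within wash baths 1, 2 and 3, r was 0.43, 0.25 and 0.3 for HFD, 0.23, -0.09 and 0.09 for CDHFD, 0.43, 0.27 and 0.52 for WD, and 0.49, 0.41 and 0.54 for WDGF. Wash bath 2, with the lowest r for each diet, holds both arrays opposing their label. The r values within baths were not repeated without these arrays. On WD, 849 probes were higher in both sexes, where independent lists would share 171.3, and 717 were lower in both, where 155.9 would be shared; 2 went opposite ways. On WDGF, 1400 were higher in both against 378.2 for independent lists and 1506 lower against 472.8, with 38 opposite. On HFD, 404 were higher against 67.1 and 819 lower against 109.3, with 3 opposite, and on CDHFD 9 were shared. Among probes past the threshold in either sex, r was 0.65 for HFD, 0.65 for CDHFD, 0.72 for WD and 0.7 for WDGF.

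**Figure D3:**
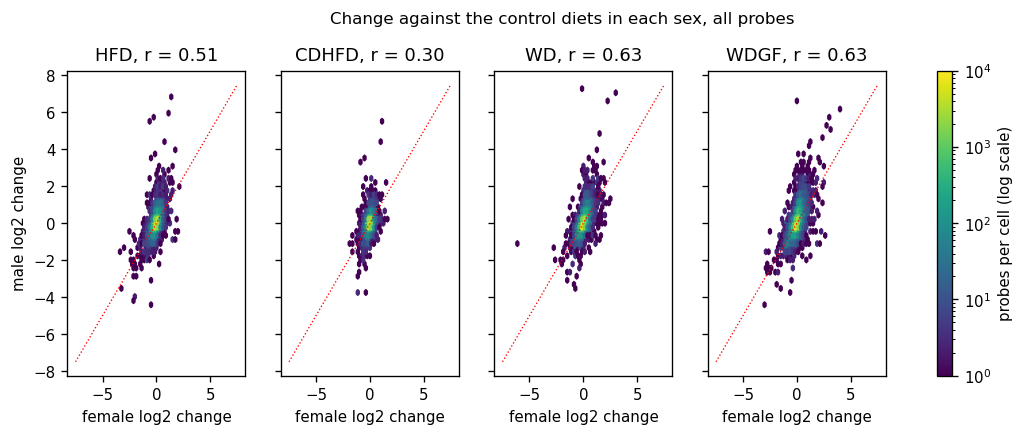
Log2 change against the control diets in males (vertical axis) and females (horizontal axis) for all 33847 probes, 1 panel per test diet, with colour for the number of probes per cell on a log scale and a dotted line where both changes are equal. The Pearson r across probes with all arrays was 0.51 for HFD, 0.3 for CDHFD, 0.63 for WD and 0.63 for WDGF. Without the 2 arrays that oppose their sex label it was 0.45, 0.3, 0.62 and 0.6.

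How far each diet moved the probe sets of another was scored per array with probes called in the other sex. The changes that define a set and the scores then come from different arrays, although all 72 arrays enter the spread and the bath term behind the calls. The score is 0.5 times the difference between the mean log2 value of the probes that rose and that of the probes that fell, set to 0 at the mean of the control diets of that sex. The HFD set, defined by the 744 higher and 1077 lower probes in females, scored 0.346 ± 0.067 in males on HFD, 0.267 ± 0.045 on CDHFD, 0.213 ± 0.035 on WD and 0.21 ± 0.063 on WDGF (SD, n = 6), each above the controls (two-sided exact permutation test, p = 5.4e-05, the smallest it can give, and 2e-04 after Benjamini-Hochberg adjustment over 48 tests). In females, with the probes called in males, the HFD set was highest on WDGF, at 0.176 ± 0.026, and scored 0.153 ± 0.025 on HFD, 0.127 ± 0.055 on WD and 0.073 ± 0.045 on CDHFD. The difference between CDHFD and HFD was -0.079 in females (95% bootstrap interval -0.113 to -0.039, exact permutation p = 0.0087, adjusted 0.017). In males the same difference was -0.079 (-0.139 to -0.02, exact permutation p = 0.035, adjusted 0.058), and -0.063 without the 2 arrays (exact permutation p = 0.067). Control2 scored below Control1 on this set in males, with a difference of -0.067 (-0.098 to -0.032, exact permutation p = 0.011, adjusted 0.02), and the difference in females was 0.005 (exact permutation p = 0.87).

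The WD set scored 0.397 ± 0.092 in males on WD, 0.464 ± 0.042 on WDGF, 0.223 ± 0.046 on HFD and 0.091 ± 0.151 on CDHFD, and the CDHFD value was not separated from the controls (two-sided exact permutation p = 0.18, adjusted 0.23). That mean depends on male CDHFD replicate 5, which scored 0.38. Without it, a test added after the data were seen, the group averaged 0.033 ± 0.057 (n = 5, range -0.028 to 0.124, unadjusted exact permutation p = 0.56 against the controls). Both tests against the controls pooled the arrays of both control diets, although Control1 averaged -0.081 and Control2 0.081 on this set. Neither control diet was tested alone, so these p-values do not show a lack of response. The difference between CDHFD and HFD on this set was -0.132 with all arrays (exact permutation p = 0.065) and -0.19 without male CDHFD replicate 5 (unadjusted exact permutation p = 0.0022). That replicate was left out for its high score on this same set, so its removal widens the difference by construction. The second p-value is therefore no separate evidence. In females the WD set scored 0.181 ± 0.056 on WD, 0.214 ± 0.041 on WDGF, 0.078 ± 0.028 on HFD and 0.043 ± 0.079 on CDHFD. WD scored above HFD by 0.175 in males (exact permutation p = 0.0022, adjusted 0.0059) and by 0.104 in females (exact permutation p = 0.0043, adjusted 0.0098). WDGF and WD differed on this set by 0.067 in males (95% bootstrap interval -0.013 to 0.133, exact permutation p = 0.15) and by 0.032 in females (-0.019 to 0.081, exact permutation p = 0.28). Control2 scored above Control1 in males by 0.162 (0.071 to 0.24, exact permutation p = 0.011, adjusted 0.02). In females the same difference was 0.05 (exact permutation p = 0.18), and 0.086 without the 2 arrays (exact permutation p = 0.017, adjusted 0.03). A set for WDGF was scored in the same way. In males it averaged 0.402 on WDGF, 0.372 on WD, 0.249 on HFD and 0.126 on CDHFD. Against the controls the CDHFD difference had an exact permutation p of 0.052 (adjusted 0.081). It was 0.137 without the 2 arrays (exact permutation p = 0.033, adjusted 0.053) and 0.086 without male CDHFD replicate 5 (unadjusted exact permutation p = 0.16). Female means were 0.168, 0.155, 0.057 and 0.035.

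**Figure D4:**
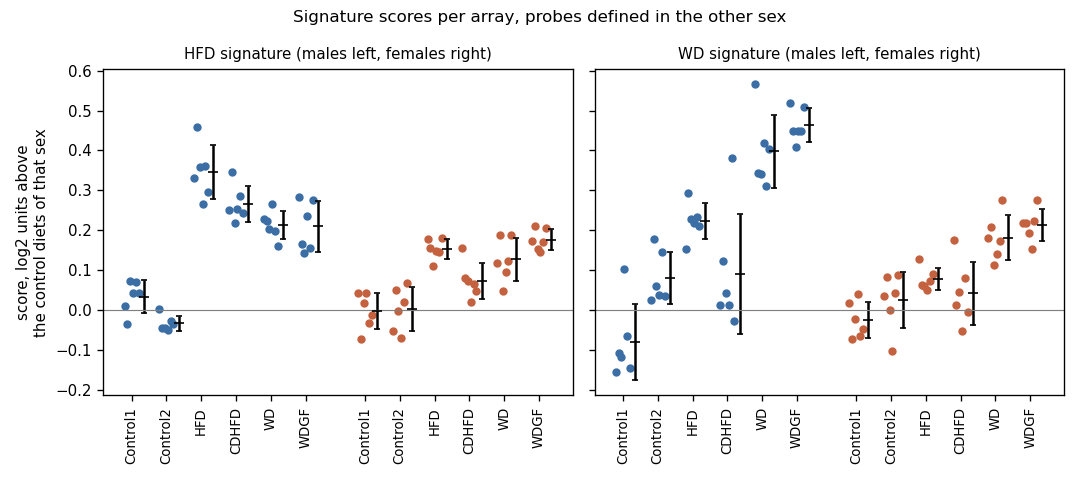
Score of each array (points) for the HFD set (left panel) and the WD set (right panel), in log2 units above the control diets of that sex, with males in blue and females in orange and the mean and SD of each group of 6 beside its points. In males the HFD set is highest on HFD, at 0.346, and the WD set is highest on WDGF, at 0.464.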

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

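The test of mixed RNA, and those that leave out the 2 arrays opposing their sex label, were chosen after the results were seen. Each of the 12 groups was searched for an array far from the others on 6 measures. Of these 72 searches 13 found one, where chance gives about 3.6 for independent measures; the measures overlap, and 8 of the 13 are the 2 arrays opposing their sex label.

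The array labelled male Control1 replicate 4 lay at -0.106 between the sexes, with its nearest group member at 0.946, and the array labelled female Control2 replicate 4 at 1.053, with its nearest at 0.058. The same arrays stood apart on the male-biased probes (8.038 against 9.884, and 9.953 against 8.264, mean log2 level) and the female-biased probes (10.503 against 8.184, and 8.317 against 10.419). Mixed RNA of both sexes is argued against, since each array lay at least 0.553 from the midpoint between the sexes. An exchange of the labels of these arrays remains a candidate explanation: on probes that separate the control diets within the sex each array resembles, 2 of 2 lay on the side such an exchange predicts, at 0 for the array labelled female Control2 replicate 4 and 0.857 for the array labelled male Control1 replicate 4, where 21 of 22 other control arrays lay on their own side, with an SD of 0.212. Both arrays were in wash bath 2, and a swap at any step from animal to array stays open.

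More probes differed from the control diets in males than in females for each test diet. A larger spread between females is argued against. Without the 2 arrays, the median SD within groups was 0.133 to 0.158 in females and 0.132 to 0.167 in males. The model gives each probe 1 spread for both sexes, with a median standard error of 0.085 in each. The SD of the changes after removal of sampling variance was at least 1.73 times higher in males in each of the 3 wash baths, averaged over diets. On CDHFD alone it was 0.166 in males and 0.137 in females in wash bath 1, 0.07 and 0.062 in bath 2, and 0.198 and 0 in bath 3. The 2 arrays opposing their label are also argued against as the cause: without them the male count was at least 3.48 times the female one. That males respond more strongly to these diets remains a hypothesis, and food intake or body weight, which could differ by sex, were not analysed here. The interaction passed for 387 probes on HFD, 71 on CDHFD, 517 on WD and 2354 on WDGF. It tests whether the signed changes differ and does not say which sex changed more in size. The male change was the more positive for 279, 50, 361 and 1319 of these probes and the more negative for 108, 21, 156 and 1035.

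Other arrays stood apart from the rest of their group in single values. On the WD set, male CDHFD replicate 5 scored 0.38 with its nearest at 0.124, and stood apart on the second principal component too, at 0.15 with the others of its group from -0.144 to -0.043. On the WD set, the array labelled male Control1 replicate 4 scored 0.103 with its nearest at -0.064. On the set of probes called for WDGF in the other sex, the array labelled male Control1 replicate 4 scored 0.055 with its nearest at -0.073, and female HFD replicate 1 scored 0.116 with its nearest at 0.059. The mean level of male-biased probes was 8.068 in female Control1 replicate 6 (nearest 7.939), 8.04 in female HFD replicate 2 (nearest 7.909) and 8.259 in female WD replicate 3 (nearest 8.147).

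Chance was tested for each comparison with 100 splits of the same arrays, the real one included. For the other splits of the sex differences, the sex difference common to the diets was first subtracted from the values. Sex labels were then exchanged within each diet only. In 15 of the 21 comparisons only the real split gave its count. The highest count among the other splits was 1932 for HFD in males (real 6486), 584 for HFD in females (1821), 2176 for CDHFD in males (2615), 988 and 886 for WD in males and females (9586 and 2329), 5404 and 194 for WDGF (13779 and 4187), 1728 and 601 for the control diets (2100 and 1542), 130 and 310 for WD against HFD (848 and 1659), 4917 between the sexes (9788), and 13, 69 and 3 for the sex difference on HFD, WD and WDGF (387, 517 and 2354). In 2 further comparisons the limit set in advance, under 5 of 100 splits, was met narrowly and without correction for the 21 comparisons, and since other splits gave more, chance is excluded only in that sense. For CDHFD against HFD in males, 4 splits reached the real 48 and the highest other gave 1038. For the sex difference on CDHFD, 3 splits reached the real 71 and the highest other gave 363. Chance was not excluded for CDHFD in females, where 5 splits reached the real 13 and the highest other gave 41, or for WDGF against WD in females, where 17 splits reached the real 1 and the highest other gave 139. In these 4 comparisons another split called several times the real count, which may reflect a structure of the samples other than the groups; its cause was not tested. Without male CDHFD replicate 5 the count of CDHFD against HFD in males went from 48 to 946, and the splits were not repeated without it. For CDHFD against HFD in females and WDGF against WD in males the real count was 0, so all 100 splits reach it and the splits say nothing (highest other 36 and 23).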

How the results depend on the processing

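The alternatives without the 2 arrays, with each array left out in turn and with probe sets from fits on the defining arrays alone were chosen after the data were seen. No exact test with an unadjusted p under 0.05 changed sign. The order of diets in females turned against Control2 alone, with 2623 calls for HFD, 2139 for WDGF and 731 for WD, and the female-biased probes in males on CDHFD, not past the threshold, went from 0.187 to -0.034 without the 2 arrays. Leaving out the wash bath term or using trend and robust settings moved no count of the 21 comparisons by over 1.5 times. The wash bath means of the deposited values were already nearly equal, so leaving out that term could change little. Repeating quantile normalization or centring on the 75th percentile moves nothing by construction on values already quantile normalized. The mean of a gene's probes and the gene list tests were not run, for want of gene names. With Control1 alone as reference, the counts were 1146 for HFD in females, 0 for CDHFD in females, 5196 between the sexes and 36 for the sex difference on CDHFD. With Control2 alone they were 186 for CDHFD in females, 5519 for WD in males, 731 for WD in females, 2139 for WDGF in females, 6414 between the sexes, and 257, 216, 322 and 1349 for the sex difference on HFD, CDHFD, WD and WDGF. The cause was not tested. Male Control1 and female Control2 each hold 1 array opposing its sex label. The counts against a single control diet, and those below with only the arrays compared, were not repeated without these arrays. Where their group was compared, they make up a larger share of the arrays in such a fit. With only the arrays compared, which leaves fewer arrays to estimate the spread, the counts were 613 for HFD in females, 1338 and 1 for CDHFD in males and females, 933 for WD in females, 410 and 58 for Control2 against Control1 in males and females, 1 for CDHFD against HFD in males, 0 for WDGF against WD in females, and 233, 25 and 344 for the sex difference on HFD, CDHFD and WD. The replicate block gave 7 for CDHFD in females, 30 for CDHFD against HFD in males, 0 for WDGF against WD in females and 192 for the sex difference on WD, and moved no other count by over 1.5 times; the numbers do not pair the samples, since 67 of 396 same-numbered pairs correlated above 0.1, the mean r was -0.0262 against 0.00526 for other numbers, and 5 of 72 arrays correlated best with their own number. Without the dimmest 25% of probes, CDHFD against HFD in males gave 28 and WDGF against WD in females 0, from fewer probes tested. The 2 arrays left out, the counts were 36 for CDHFD in females, 2704 for Control2 against Control1 in females, 117 and 1 for CDHFD against HFD in males and females, and 843, 142, 847 and 3827 for the sex difference on HFD, CDHFD, WD and WDGF. With 1 array left out, the lowest and highest counts were 1157 and 1968 for HFD in females, 1712 and 2675 for CDHFD in males, 4 and 19 for CDHFD in females, 924 and 2650 for WD in females, 1367 and 2816 for Control2 against Control1 in males and 603 and 2297 in females. They were 3 and 946 for CDHFD against HFD in males and 0 and 3 in females, 0 and 17 for WDGF against WD in males and 0 and 2 in females, and 499 and 982 for WD against HFD in males. For the sex difference they were 229 and 551 on HFD, 43 and 99 on CDHFD, and 273 and 678 on WD. The correlation between the sexes over probes past the threshold in either sex was 0.65 for HFD, 0.65 for CDHFD and 0.7 for WDGF, a set selected for large changes. Of the exact tests of scores and sex-biased probes, 4 lost and 4 gained an unadjusted p under 0.05 without the 2 arrays. With probe sets from the defining arrays alone, 0 lost and 1 gained it among the 48 tests of scores, and 0 did either among the 16 tests of sex-biased probes. Detection calls were not used here, so signal over background sets an unknown limit on dim probes.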

Other observations

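Probes that differ between the sexes also changed with diet in males. The sets were fixed from the Control1 groups, as probes called between males and females and at least 2-fold apart, and were followed against Control2. The means of the 2 steps come from different arrays, although all arrays enter the spread and the bath term behind the calls. The sets were chosen after the data were seen, as were the tests without the 2 arrays opposing their sex label and with sets from Control1 arrays alone; the test of female RNA was set before its result. With all arrays the sets held 219 male-biased and 241 female-biased probes. In males on WDGF, the mean level of the female-biased probes was 9 ± 0.159 against 8.492 ± 0.175 on Control2 (SD, n = 6), a difference of 0.508 log2 units (two-sided exact permutation p = 0.0022, the smallest it can give, adjusted 0.012 over 16 tests), and 85 of the 241 rose while 20 fell. The male-biased probes changed by -0.481 (exact permutation p = 0.0087, adjusted 0.028), with 17 higher and 90 lower. With the sets fitted on the Control1 arrays alone, the female-biased and male-biased probes changed by 0.562 and -0.498 (exact permutation p = 0.0022 and 0.0087, adjusted 0.012 and 0.02). HFD moved the sets by 0.48 and -0.437 in males (exact permutation p = 0.0022 and 0.0065, adjusted 0.012 and 0.026). Without the 2 arrays the HFD values were 0.311 and -0.377 (exact permutation p = 0.0022 and 0.0065, adjusted 0.018 and 0.021). On CDHFD the differences were 0.187 and -0.198 (exact permutation p = 0.17 for each), the first of which was -0.034 without the 2 arrays (exact permutation p = 0.8), and on WD 0.271 (exact permutation p = 0.017, adjusted 0.039) and -0.164 (exact permutation p = 0.25).

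A reduced sex bias in males on WDGF is a hypothesis, and technical sources were weighed for that diet. HFD moved both sets in males too. Without the 2 arrays opposing their label, WD moved the female-biased probes by 0.317 (exact permutation p = 0.0043, adjusted 0.021). The male-biased probes changed by -0.168 on WD (exact permutation p = 0.22). WDGF was not tested against HFD or WD on these sets, so the shift is not shown to be particular to WDGF. Female RNA in the male WDGF samples is argued against: of the 10 probes with the largest female over male difference, 4 changed by less than 0.2 log2 units, and 3 rose, A_51_P467076 by 4.2, A_55_P2044653 by 3.76 and A_52_P289091 by 2.19. The 2 arrays opposing their label are argued against as the cause, since without them the sets held 299 and 450 probes and the female-biased probes were still 0.561 higher in males on WDGF (exact permutation p = 0.0022, adjusted 0.018), with 234 higher and 41 lower. Changes in hormones or growth may lie behind the shift and were not measured here.

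In females the same sets cannot be read with all arrays, because the array labelled female Control2 replicate 4 widens the Control2 spread to 0.731 and 0.885. Without the 2 arrays, the male-biased probes changed by -0.208 in females on HFD (two-sided exact permutation p = 0.0065, adjusted 0.021), and the female-biased probes by 0.019 (exact permutation p = 0.76).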
